A study of Homo sapiens with 208 samples.

How the data were processed

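ChIP-seq libraries of human RPE cells were sequenced single-end, per the labels' protocols, after harvest of sub-confluent plates. Per the submitters' processing notes, BWA, SAMtools and HOMER 4.8 were used and the build was hg19; which tool did what, and the thresholds, are not given in the sources used here. The deposited peak lists give a chromosome, a start and an end per peak, with no header, score or read number. Peaks were listed per library, so each replicate has its own list. Within a list no peaks overlapped, the smallest gap was 500 bp, and between 15.4% and 51.6% of peaks were exactly 500 bp wide. No read totals are in the lists, so the depth is unknown, no counting interval can be given, and how much was called cannot be separated from how much was marked.

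The unit of the deposited lists is other than a count, since they hold positions in bp alone. Samples were grouped by mark, genotype, phase and replicate number as the labels give them. Of 208 samples, 80 have a peak list used here; the remaining 128, which cover other marks and input, were not analysed here. Background in the input was therefore not compared. Covered length is the summed width of a library's peaks. Consensus regions are stretches in peaks of at least 2 of a mark's 16 libraries, with gaps up to 500 bp joined and a width of at least 200 bp. A region was present in a library with at least 1 bp in a peak. Regions on chromosome Y were left out of the region, similarity and window tests. Coordinates are 1-based on hg19.

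The tests, threshold, alternatives and rule for named regions were fixed before the data were examined. Log2 covered length was compared between genotypes by a two-sided exact permutation of genotype within phase, and between phases by an exact permutation of phase within genotype. The dependence of the genotype difference on phase was tested by an exact permutation of phase over differences paired by replicate number. Regions present in 5 to 11 libraries were tested by Fisher's exact test for genotype, and those present in 3 to 13 libraries by the exact Fisher-Freeman-Halton test for phase. Jaccard indices, the share of a mark's length in peaks of another mark (8 tests) and chromosome shares were compared by exact permutation. Each family was adjusted by the Benjamini-Hochberg method at 0.05. For each mark and factor the rule named up to 3 regions per direction past the threshold, ranked by adjusted p, then by the difference in mean covered length, then by position, and otherwise at most 1 leading region per direction, which for phase is given as 1 in all.

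Alternatives were a replicate block, the number of peaks, the median width, the widest 50% of each list, Ctrl alone, phase as strata, at least 50% of a region in peaks, regions seen in at least 4 libraries, 1 kb bins, the same number of widest peaks from every library, other overlap measures and leaving out each library. Peak width stood in for a score in the stricter settings, because the lists hold no score. Some analyses were chosen after the data were seen: regions with a peak in all 8 libraries of 1 genotype and none of the other, leaving out the 2 libraries with the least covered length, leave-one-out for results where it was not planned, and 1 Mb windows. For the windows, covered bp was scaled to the library's total, 1000 bp was added, and log2 values of windows with a mean of at least 5000 bp were fitted with limma 3.58.1 in R 4.3.3, with phase and genotype in the model. A first exploration of the windows scaled to chromosomes 1 to 22 and X alone; it is kept as an alternative.

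The promoter analysis of 10 gene lists, with its 2 transcription start distances, and any value for KDM4A itself were not run: the gene table used is of assembly GRCh38.p14, coordinates were not converted between builds, and no hg19 annotation was used here. Whether the libraries labelled KDM4A-OE overexpress the gene was therefore not checked.

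The functions were tested on simulated data. Of 200 changed regions present in 99% of libraries of 1 genotype and 1% of the other, Fisher's exact test recovered 99.5% among 8000 regions and 84.0% among 40000. With presence in 85% against 15% it recovered 7.50% among 8000 regions and 0 among 40000. The phase test recovered 0 of 200 regions present in 1 of 4 phases among 8000 regions, and 1916 when 2000 regions were changed. The window model recovered 97.5% of 200 windows changed by a log2 value of 1 among 2300. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.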

Results

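Histone marks were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in cultured human retinal pigmented epithelial (RPE) cells. The cells were either a control line (Ctrl) or a line that stably overexpressed KDM4A, a lysine demethylase known to act on methylated lysines 9 and 36 of histone H3 (KDM4A-OE). Both were sampled in 4 cell cycle phases, G1, early S, late S and G2/M, with 2 replicates per group. Peak lists of 5 marks were analysed, H3K4me1, H3K4me2, H3K4me3, H3K9ac and H3K27ac, in 80 libraries that form 40 groups, or 16 libraries per mark. H3K4me1 and H3K27ac are commonly found at enhancers, H3K4me3 and H3K9ac at promoters, and H3K4me2 at both. The other 128 samples of the series were not analysed here. The lists held 4471738 peaks in all and between 17097 and 105179 per library. They carry no read number or peak score, so the sequencing depth behind each list is unknown, and a library with fewer peaks cannot be told from one sequenced or enriched less. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

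H3K4me1 and H3K4me2 covered the most genome and H3K4me3 the least. Over the 16 libraries of a mark, peaks covered 114 ± 45.5 Mb for H3K4me1, 120 ± 27.8 Mb for H3K4me2, 93.6 ± 22.9 Mb for H3K27ac, 45.1 ± 10.3 Mb for H3K9ac and 42.8 ± 7.10 Mb for H3K4me3 (SD, n = 16 each). Stretches in peaks of at least 2 libraries gave 118790 consensus regions for H3K4me1, 108418 for H3K4me2, 80518 for H3K27ac, 54033 for H3K9ac and 34683 for H3K4me3. H3K4me3 was the most constant mark: 12025 of its regions, or 34.7%, had a peak in all 16 libraries, against 26.2% for H3K4me2, 23.5% for H3K27ac, 20.99% for H3K9ac and 10.0% for H3K4me1. The widest constant H3K27ac region lay on chromosome 10 from 80829245 to 80957469 (hg19), where KDM4A-OE libraries covered 113392 ± 10766 bp and Ctrl libraries 109126 ± 20494 bp (SD, n = 8 each). The widest constant H3K4me1 region, on chromosome 10 from 80831132 to 80925454, lay inside it. On chromosome 7, a region from 130577294 to 130604131 was among the widest constant H3K4me3 regions, with 23153 ± 1657 bp covered in KDM4A-OE and 20078 ± 6300 bp in Ctrl libraries (SD, n = 8 each). Constant H3K4me2 and H3K9ac regions also covered it. Gene names are not given to regions, because no annotation of hg19 was used here.

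The first comparison asked whether KDM4A overexpression changed how much of the genome each mark occupied. No mark differed between the genotypes past the spread between libraries when the 4 phases were pooled. H3K4me3 came nearest, with 46.1 ± 3.08 Mb in KDM4A-OE and 39.4 ± 8.56 Mb in Ctrl (SD, n = 8 each), a log2 difference of 0.26 with KDM4A-OE higher in 7 of 8 same-numbered comparisons (two-sided exact permutation p = 0.0602, adjusted p = 0.301). The log2 difference was -0.07 for H3K4me1 (exact permutation p = 0.866, adjusted p = 0.866), -0.11 for H3K4me2 (exact permutation p = 0.611, adjusted p = 0.816), 0.09 for H3K9ac (exact permutation p = 0.634, adjusted p = 0.816) and 0.10 for H3K27ac (exact permutation p = 0.653, adjusted p = 0.816). Single libraries turned 3 of these signs. Without the KDM4A-OE early S replicate 1 library the difference was 0.17 for H3K4me1 and 0.05 for H3K4me2, and without the KDM4A-OE G2/M replicate 1 library it was 0.153 for H3K4me1. For H3K9ac it was -0.01 without Ctrl G2/M replicate 1 and -0.01 without KDM4A-OE early S replicate 2. Without the Ctrl late S replicate 2 library, the H3K4me3 difference was 0.35, with an exact permutation adjusted p of 0.0463. Without the Ctrl late S replicate 1 library it was 0.16. The same-numbered H3K4me3 differences in G1, early S, late S and G2/M were 0.85, 0.18, 0.59 and 0.32 in replicate 1. In replicate 2 they were 0.13, 0.01, -0.11 and 0.06, so most of the difference lay in replicate 1. There, Ctrl libraries covered 26.6 to 38.7 Mb, against 43.2 to 48.9 Mb in Ctrl replicate 2.

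**Figure D1:**
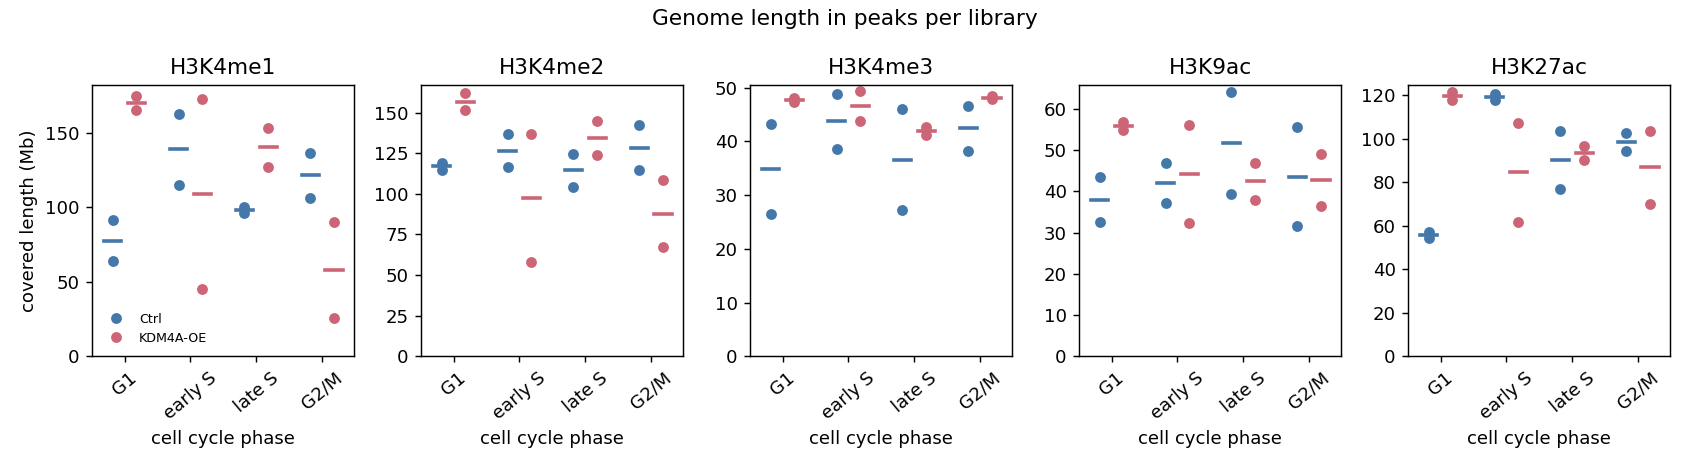
Genome length in peaks (Mb, vertical axis from 0) in each library, by cell cycle phase (horizontal axis), for the 5 marks. Points are libraries, bars are means of 2 libraries, blue is Ctrl and red is KDM4A-OE; in G1 both KDM4A-OE libraries lie above both Ctrl libraries for every mark.

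Within phases the genotypes lay apart in different directions. In G1, both KDM4A-OE libraries covered more genome than both Ctrl libraries for all 5 marks, from 1.34-fold for H3K4me2 to 2.22-fold for H3K4me1. H3K27ac covered 119.7 ± 2.45 Mb in KDM4A-OE and 55.8 ± 2.15 Mb in Ctrl G1 cells (SD, n = 2 each). In G2/M, both KDM4A-OE libraries lay below both Ctrl libraries for H3K4me1, with 57.9 ± 45.2 Mb against 121 ± 21.2 Mb, and for H3K4me2, with 87.7 ± 29.3 Mb against 128 ± 19.6 Mb (SD, n = 2 each). In early S they lay below for H3K27ac, with 84.7 ± 32.2 Mb against 119 ± 2.01 Mb (SD, n = 2 each). In late S they lay above for H3K4me1, 1.42-fold, and in G2/M for H3K4me3, 1.14-fold. A single phase has 2 libraries against 2 and cannot give an exact two-sided p below 0.333, so these values were not tested one by one. Whether the genotype difference depended on phase was tested over the 8 same-numbered differences of each mark. Same-numbered replicates were not shown to be paired, so the shares that follow depend on this pairing by number. Phase held 84.1% of their variance for H3K27ac (exact permutation p = 0.0571, adjusted p = 0.286), 76.5% for H3K4me1 (exact permutation p = 0.124, adjusted p = 0.310) and 68.9% for H3K4me2 (exact permutation p = 0.257, adjusted p = 0.429). For H3K9ac and H3K4me3 the shares were 40.8% and 23.7% (exact permutation adjusted p = 0.643 and 0.781). Phase also holds a share of variance with no effect, which is 50.0% on average when 1 pair is left out. These last 2 shares moved with single pairs. For H3K9ac the share was 22.4% without G1 replicate 1, 81.9% without G2/M replicate 1 and 78.4% without G2/M replicate 2. For H3K4me3 it was 7.56% without G1 replicate 1, 58.5% without G1 replicate 2, 48.1% without late S replicate 1 and 46.4% without late S replicate 2. No mark passed the adjusted threshold.

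Single regions were compared by the number of libraries with a peak, 8 KDM4A-OE against 8 Ctrl. H3K4me3 gave the only calls: 31 of 8109 tested regions had a peak in all 8 KDM4A-OE libraries and in no Ctrl library, and none was called lower (Fisher's exact test, adjusted p = 0.0406). The 3 leading regions lay on chromosome 17 from 39264293 to 39267530, on chromosome 8 from 16606649 to 16609223 and on chromosome 7 from 69063643 to 69065337 (hg19). KDM4A-OE libraries covered 2399 ± 1012 bp, 1959 ± 571 bp and 1363 ± 260 bp of them, and Ctrl libraries 0 bp (SD, n = 8 each). These calls lay close to the threshold, and their number was 0 with the same number of widest peaks taken from every library, with at least 50% of a region required in peaks, with 1 kb bins, with the 2 least-covered libraries left out and without any 1 of 6 single libraries: Ctrl late S replicate 1, both KDM4A-OE G1 replicates, KDM4A-OE early S replicate 2 and both KDM4A-OE G2/M replicates. Leaving out 1 library cannot change the direction of the 3 leading regions, which had a peak in 8 libraries against 0. Only their adjusted p could change, and it lay between 0.0368 and 0.0528, on both sides of the threshold (Fisher's exact test). Without either Ctrl G1 replicate, 1 H3K4me3 region was called lower. The leading H3K4me3 region in that direction, on chromosome 20 from 6991230 to 6992373, had a peak in 7 Ctrl libraries and no KDM4A-OE library (Fisher's exact test, adjusted p = 0.133).

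No region of the other 4 marks passed Fisher's exact test after adjustment. The smallest p of this test is 1.55e-04, so passing depends on how many regions reach it among those tested. For H3K4me2, 3 regions in all 8 KDM4A-OE libraries alone and 36 in all 8 Ctrl libraries alone reached it, among 29643 tested. For H3K27ac 11 and 0 did, among 20256. H3K4me3 was thus the only mark called but not the only one with such regions. At an unadjusted p under 0.05 there were 1142 H3K4me1, 1495 H3K4me2, 503 H3K9ac and 778 H3K27ac regions. These were 2.62%, 5.04%, 3.36% and 3.84% of the tested regions. The leading H3K4me2 region, on chromosome 4 from 161510649 to 161517470, covered 4784 ± 743 bp in Ctrl libraries and 0 bp in KDM4A-OE libraries (SD, n = 8 each; Fisher's exact test, adjusted p = 0.118). The leading H3K4me2 region in the other direction lay on chromosome 5 from 27315087 to 27317137, with 1708 ± 355 bp in KDM4A-OE and 0 bp in Ctrl libraries (SD, n = 8 each; Fisher's exact test, adjusted p = 0.118). For H3K27ac, a region on chromosome X from 151149673 to 151155244 had a peak in the 8 KDM4A-OE libraries alone (Fisher's exact test, adjusted p = 0.286). A region on chromosome 1 from 217202217 to 217203920 had an H3K27ac peak in 8 Ctrl libraries and 1 KDM4A-OE library (Fisher's exact test, adjusted p = 0.746). For H3K9ac, a region on chromosome 6 from 26235019 to 26235817 had a peak in the 8 KDM4A-OE libraries alone and one on chromosome 20 from 22842055 to 22843086 in the 8 Ctrl libraries alone (Fisher's exact test, adjusted p = 1.0000 for both). For H3K4me1 the leading regions were on chromosome 7 from 68011410 to 68013323, with a peak in the 8 KDM4A-OE libraries alone, and on chromosome 1 from 107297709 to 107299469, with a peak in the 8 Ctrl libraries alone (Fisher's exact test, adjusted p = 1.0000 for both).

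**Figure D2:**
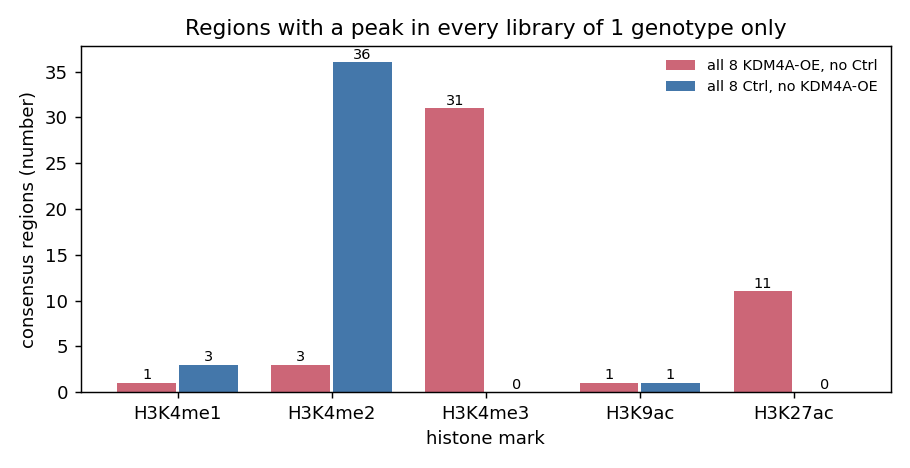
Number of consensus regions (vertical axis from 0) of each mark (horizontal axis) with a peak in all 8 libraries of 1 genotype and in none of the other; red bars are KDM4A-OE and blue bars Ctrl. H3K4me3 has 31 such regions in KDM4A-OE and 0 in Ctrl, and H3K4me2 has 3 and 36.

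H3K4me3 regions of this kind clustered on chromosome 1 from 44121082 to 44149742 (hg19), a stretch singled out after its values were seen. The stretch holds 2 of the 31. With flanks of 50000 bp, it held 15 H3K4me3 regions, of which 11 had a peak in all 8 KDM4A-OE libraries, and 9 of these 11 also had one in 2 to 8 Ctrl libraries.

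**Figure D3:**
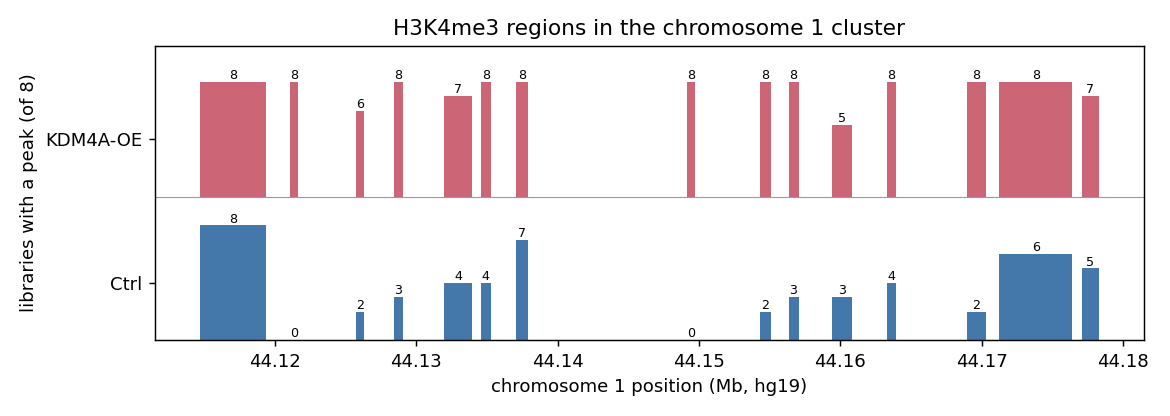
H3K4me3 consensus regions in and around a cluster on chromosome 1 (horizontal axis, Mb on hg19), with the number of libraries out of 8 that have a peak (bar height from 0) in KDM4A-OE (red) and in Ctrl (blue). The stretch was chosen for 2 of these regions.

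The second comparison asked whether the marks followed the cell cycle. With both genotypes pooled, phase held between 3.98% (H3K9ac) and 17.9% (H3K4me3) of the variance of log2 covered length, and no mark passed (exact permutation adjusted p = 0.919 for each mark). Phase holds some share with no effect as well, and more within 1 genotype than with both pooled. With 1 library left out these shares ran from 0.427%, for H3K4me1 without KDM4A-OE G2/M replicate 1, to 36.01%, for H3K4me3 without Ctrl late S replicate 2, so their order among marks is not fixed. In Ctrl cells alone, H3K27ac covered 55.8 ± 2.15 Mb in G1, 119 ± 2.01 Mb in early S, 90.4 ± 19.0 Mb in late S and 98.5 ± 5.82 Mb in G2/M (SD, n = 2 each). Phase held 92.6% of its variance there (exact permutation p = 0.0476, adjusted over the 5 marks p = 0.238). In Ctrl cells phase held 71.3% for H3K4me1 (exact permutation p = 0.0952, adjusted p = 0.238), 25.6% for H3K4me2, 23.7% for H3K4me3 and 19.9% for H3K9ac (exact permutation p = 0.752, 0.724 and 0.790, adjusted p = 0.790 for each). In KDM4A-OE cells alone phase held 43.4% of the H3K27ac variance (exact permutation p = 0.429, adjusted p = 0.536), 52.4% for H3K4me1, 52.1% for H3K4me2, 74.7% for H3K4me3 and 34.3% for H3K9ac (exact permutation p = 0.267, 0.238, 0.162 and 0.581, adjusted p = 0.444 for the first 3 and 0.581).

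No single region differed between phases after adjustment in any of the 5 marks. The regions at an unadjusted p under 0.05 in the exact Fisher-Freeman-Halton test numbered 639 for H3K4me1, 678 for H3K4me2, 178 for H3K4me3, 282 for H3K9ac and 488 for H3K27ac. These were 0.849%, 1.28%, 1.17%, 1.01% and 1.24% of the tested regions, fewer than this threshold allows without any effect. The leading H3K9ac region, on chromosome 3 from 20098268 to 20099066, had a peak in all 4 libraries of G1 and of late S and in none of early S or G2/M (exact p = 4.66e-04, adjusted p = 1.0000). An H3K4me3 region on chromosome 12 from 57487644 to 57488684 had a peak in the 4 early S libraries alone (exact p = 0.0022, adjusted p = 1.0000). An H3K4me1 region on chromosome 8 from 67971725 to 67973750 had a peak in all libraries but the 4 of G2/M (exact p = 0.0022, adjusted p = 1.0000). H3K4me2 on chromosome 11 from 78054670 to 78056648 and H3K27ac on chromosome 8 from 141799697 to 141802927 had a peak in all libraries but the 4 of late S (exact p = 0.0022 and adjusted p = 1.0000 for both). The smallest p this test can give is 4.66e-04, and in simulated data it recovered 0 of 200 regions present in 1 phase alone. Of 200 present in 2 of 4 phases it recovered 85.5% among 8000 regions and 0 among 40000. With 2000 changed regions present in 1 phase it recovered 95.8% among 8000 and 1693 among 40000, and with 2000 present in 2 phases 1981 in both. These counts of 0 therefore leave room for a small number of regions that followed the cell cycle. They leave less room for a large number with such clear presence only where the simulations apply. The 8000 and 40000 count all simulated regions, of which only those present in 3 to 13 libraries were tested. H3K4me1, H3K4me2, H3K9ac and H3K27ac had 118790, 108418, 54033 and 80518 regions in all, so the simulations do not cover these marks. The simulated libraries also did not differ in how much was called, as the real ones do.

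Whole peak sets of replicates were closer to each other than to those of the other genotype by small amounts in all 5 marks. Against other phases they were closer for H3K4me1, H3K4me2 and H3K27ac and less alike for H3K4me3 and H3K9ac, by differences of -0.0152 and -0.0088. For H3K4me1 the Jaccard index, the shared length as a fraction of the joint length, was 0.455 ± 0.160 between replicates (SD, n = 8 pairs), 0.413 ± 0.134 between genotypes within a phase (SD, n = 16 pairs) and 0.444 ± 0.1497 between phases within a genotype (SD, n = 48 pairs). For H3K27ac the same 3 values were 0.559 ± 0.0544, 0.517 ± 0.0902 and 0.534 ± 0.0798. For H3K4me3 they were 0.640 ± 0.0824, 0.637 ± 0.0818 and 0.656 ± 0.0720. Replicates exceeded the other genotype by between 7.90e-04 (H3K9ac) and 0.0422 (H3K27ac), and no mark passed (one-sided exact permutation adjusted p between 0.278 and 0.407). The H3K27ac difference was 0.0101 without KDM4A-OE G1 replicate 1, and the H3K4me3 and H3K9ac differences turned negative without some single libraries, to -0.0136 without KDM4A-OE G1 replicate 2 and -0.0164 without KDM4A-OE G1 replicate 1. For phase the adjusted p lay between 0.490 and 0.798 in the one-sided exact permutation test.

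With the 4 phases pooled, promoter-type and enhancer-type marks overlapped to a similar mean degree in both genotypes. Of H3K4me3 peak length, 62.6 ± 7.18% lay in H3K9ac peaks of the same group and replicate number in Ctrl and 61.4 ± 9.72% in KDM4A-OE, and 68.6 ± 11.6% and 71.0 ± 7.50% lay in H3K27ac peaks (SD, n = 8 each). Of H3K4me1 peak length, 49.9 ± 8.85% in Ctrl and 50.4 ± 6.94% in KDM4A-OE lay in H3K27ac peaks (SD, n = 8 each). Of H3K4me2 peak length, 60.5 ± 9.48% in Ctrl and 58.6 ± 21.1% in KDM4A-OE lay in H3K4me1 peaks (SD, n = 8 each). The exact permutation adjusted p was 0.897 for each of these 4 genotype comparisons. The share of H3K4me1 length in H3K27ac peaks was 44.1 ± 7.31% in G1 and 56.5 ± 7.07% in G2/M (SD, n = 4 each), and phase held 35.0% of its variance (exact permutation p = 0.181, adjusted p = 0.897).

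Shares of covered length per chromosome moved by small amounts. None of the 115 tests of a chromosome and mark passed after adjustment, and 30 had an unadjusted exact permutation p under 0.05, of which 15 were higher and 15 lower in KDM4A-OE. Chromosome 6 took 5.61 ± 0.0717% of H3K4me2 length in Ctrl and 5.81 ± 0.0987% in KDM4A-OE (SD, n = 8 each; exact permutation p = 0.0015, adjusted p = 0.0887). Chromosome 19 took 6.02 ± 0.274% of H3K4me3 length in Ctrl and 5.66 ± 0.167% in KDM4A-OE (SD, n = 8 each; exact permutation p = 0.0123, adjusted p = 0.127). Chromosomes 9, 16, 17, 19 and 22 had a lower mean share in KDM4A-OE of covered length for all 5 marks, and chromosomes 3, 4, 6, 13, 15 and 18 a higher one. By share of the number of peaks, of these chromosomes 16, 17, 19 and 22 were lower and 3 and 6 higher for all 5 marks, and the others were not.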

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

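The test of the called amount for each of the first 2 patterns weighed, the test of an added gene copy, the count of fully separated regions and all counts of other splits were chosen only after the result was seen.

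In G2/M, the H3K4me1 library of Ctrl replicate 2 had 46.0% of its length in H3K27ac peaks of the same group and replicate number, and its gap to the next of the 4 values took 0.837 of their range. In early S, the H3K4me3 library of KDM4A-OE replicate 1 had 54.9% of its length in H3K27ac peaks, with a gap of 0.921 of the range. These were 2 of 54 groups examined for a sample far from the others, and chance alone marks about 1 in 20.

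In 4 cases both KDM4A-OE libraries covered more than both Ctrl libraries in 1 phase and less than both in another. For H3K4me1 the log2 difference was higher in G1 than in G2/M by 2.47 and higher in late S than in G2/M by 1.83. For H3K4me2 it was higher in G1 than in G2/M by 1.00, and for H3K27ac higher in G1 than in early S by 1.65. By same-numbered differences alone, H3K9ac also turned, with 0.75 and 0.39 in G1 and -0.05 and -0.45 in late S, where the libraries overlapped. The difference between these pairs of phases was not tested; the exact permutation test over all 4 phases gave adjusted p = 0.286 for H3K27ac, 0.310 for H3K4me1 and 0.429 for H3K4me2.

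The dependence of the genotype difference on phase could stem from how much was called in single libraries. A single library cannot be told apart from a shared change: with any 1 of the 8 pairs left out, phase held at least 76.3% of the variance of the H3K27ac difference, but no effect would give 50.0% on average with 7 pairs in 4 phases, and the exact permutation p was up to 0.114, so the bound of 70% set beforehand was too low. Nor can a wider difference in calling: with the same number of widest peaks per library, regions present in both G1 libraries of 1 genotype and neither of the other outnumbered the higher of the other splits by 3.63 times for H3K27ac, 2.41 for H3K4me2, 2.10 for H3K4me1 and 1.71 for H3K9ac, but by 1.10 times for H3K4me3, and in H3K4me2 both directions were common (2679 in KDM4A-OE alone, 2103 in Ctrl alone). In early S, the other phase of the H3K27ac difference, 834 and 1435 such regions stood against 2776 for the split by replicate number, so the excess was not seen there; the lists give no depth, and each group has 2 libraries. An effect of KDM4A on the marks in G1 and a difference between the 2 cell lines that predates KDM4A stay open as well and were not tested.

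The 31 H3K4me3 regions called higher in KDM4A-OE may reflect a larger called amount in those libraries. Of the regions at an unadjusted p under 0.05 in Fisher's exact test, 97.7% were higher in KDM4A-OE with all peaks and 75.9% with the same number of widest peaks, where no region passed. The excess shrank without vanishing, so the called amount and an effect of KDM4A cannot be told apart. Of 100 splits of the 16 libraries, only the real split gave 31 called regions and the highest other gave 0. With all peaks, so large a count was thus rare among the splits where the mark is read alone, without adjustment over the marks. Chance is not excluded by this, since 1 of 100 is the smallest share that 100 splits can give. The other splits were not kept balanced within phase, as the real one is. A difference in calling between the genotypes cannot be excluded.

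Of the 31, 2 formed a cluster on chromosome 1 from 44121082 to 44149742 (hg19). Reads from an added copy of the overexpressed gene are a candidate explanation, since KDM4A lies on chromosome 1, but whether the cluster overlaps it was not tested because no hg19 annotation was used here. Of 48 regions of the other 4 marks in the cluster and flanks of 50000 bp, 2 had a peak in at least 6 KDM4A-OE and at most 2 Ctrl libraries and 0 had one in all 8 KDM4A-OE and no Ctrl library; 25 had a peak in more KDM4A-OE than Ctrl libraries and 7 in fewer. An added copy cannot be told apart from a local change in H3K4me3, because the regions of other marks leave both open.

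The other region tests called 0 regions, a count that each of the 100 splits reaches by definition (100 of 100), so the splits say nothing about chance there. This holds for genotype in H3K4me1 (highest other split 140), H3K4me2, H3K9ac and H3K27ac (highest other 0 for each) and for phase in each of the 5 marks (highest other 0). The H3K4me1 split with 140 regions points to a structure of the samples that was not identified; with the same number of widest peaks the highest other split gave 0.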

How the results depend on the processing

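Leaving out the 2 libraries with the least covered length, fully separated regions, all window settings and leave-one-out for similarity, co-occurrence, chromosome shares and the dependence on phase, and the replicate block for chromosome shares, were chosen only after the data were seen; the other alternatives were planned.

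Covered length by phase, its interaction with genotype, co-occurrence by phase, chromosome shares and regions by phase stayed on their side of the threshold under every alternative run. Leaving out 1 library still moved the share of variance between phases: to between 0.427% and 24.7% for H3K4me1, 10.8% and 25.1% for H3K4me2, 12.3% and 36.01% for H3K4me3, 2.81% and 13.0% for H3K9ac, and 1.82% and 26.6% for H3K27ac. Covered length by genotype kept its direction in 20 of 25 alternatives other than leave-one-out. The 5 values that turned are given next, and those that kept their direction are not, whatever their size. Without the 2 least-covered libraries its log2 difference was 0.40 for H3K4me1, 0.13 for H3K4me2 and -0.23 for H3K27ac, where both Ctrl G1 libraries drop out. By the number of peaks it was 0.0062 for H3K4me2, and by median width -0.12 for H3K4me3. Adjusted exact permutation p over these alternatives lay between 0.195 and 0.957. Leaving out 1 library gave -0.31 to 0.17 for H3K4me1, -0.26 to 0.0481 for H3K4me2, 0.16 to 0.35 for H3K4me3, -0.0128 to 0.19 for H3K9ac and 0.0033 to 0.20 for H3K27ac. The cause was not tested.

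The 31 H3K4me3 regions became 0 with replicate number as a block, with phase as strata, with at least 50% of a region in peaks, with 1 kb bins, with the same number of widest peaks and without the 2 least-covered libraries. The smallest p of the block is 0.0078 and of the strata 0.0015, and 31 regions reached each. At that p alone, 155 of the 992 regions tested would be needed for the block and 190 of 6152 for the strata, so these 2 counts of 0 say little about stability. The 2 least-covered H3K4me3 libraries were both Ctrl, G1 replicate 1 (26.6 Mb) and late S replicate 1 (27.3 Mb). Without them the smallest p of Fisher's exact test is higher as well, so that count of 0 also says little about stability. For the rest the cause was not tested. Regions seen in at least 4 libraries gave 31. Leaving out 1 library gave 0 to 44 higher and 0 to 1 lower. The 3 leading regions kept a difference of 100 percentage points by construction, and their adjusted p lay between 0.0368 and 0.0528 in Fisher's exact test. Counting fully separated regions in place of the test gave 1 higher and 3 lower for H3K4me1, 3 and 36 for H3K4me2, 1 and 1 for H3K9ac and 11 higher for H3K27ac. With the same number of widest peaks as well, it gave 5 and 2 for H3K4me1, 6 and 41 for H3K4me2, 7 higher for H3K4me3, 2 higher for H3K9ac, and 10 and 2 for H3K27ac.

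Leaving out 1 library moved the similarity difference for genotype between 0.0091 and 0.0952 for H3K4me1, 0.0080 and 0.0602 for H3K4me2, -0.0136 and 0.0322 for H3K4me3, -0.0164 and 0.0182 for H3K9ac, and 0.0101 and 0.0618 for H3K27ac. For phase it lay between -0.0175 and 0.0520 for H3K4me1, -0.0179 and 0.0360 for H3K4me2, -0.0227 and 0.0085 for H3K4me3, -0.0224 and 0.0082 for H3K9ac, and 0.0155 and 0.0444 for H3K27ac. The genotype difference in co-occurrence, in percent, lay between -4.31 and 1.98 for H3K4me3 in H3K9ac, -0.21 and 5.05 for H3K4me3 in H3K27ac, -1.16 and 2.21 for H3K4me1 in H3K27ac, and -7.44 and 3.66 for H3K4me2 in H3K4me1. None of these passed the threshold, and the cause of the turned signs was not tested.

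Counts of windows by genotype depended strongly on the setting. With log2 covered length as a covariate they were 181 for H3K4me1, 445 for H3K4me2, 8 for H3K4me3, 1 for H3K9ac and 16 for H3K27ac. By phase they were 1 for H3K4me1 and 4 for H3K27ac. Of the 10 H3K4me3 windows of the main setting, only 2 still passed. They lay at 44000001 to 45000000 on chromosome 1 and 63000001 to 64000000 on chromosome 10 (limma adjusted p = 0.0234 and 0.0465). With phase and replicate number as a block they were 265 for H3K4me2, 166 for H3K4me3, 1 for H3K9ac and 17 for H3K27ac. A pseudocount of 100 bp gave 6 for H3K4me1. A mean of at least 20000 bp gave 3 for H3K4me1, 6 for H3K4me3 and 0 for H3K27ac, and 2 by phase for H3K27ac. The same number of widest peaks gave 1 for H3K4me1 and 16 for H3K4me3. Without the 2 least-covered libraries there were 74 for H3K4me1, 389 for H3K4me2 and 0 for H3K4me3, and by phase 20 for H3K4me1 and 1 for H3K27ac. Leaving out 1 library gave 5 to 30 for H3K4me1, 73 to 413 for H3K4me2, 0 to 171 for H3K4me3, 0 to 2 for H3K9ac and 0 to 18 for H3K27ac, and by phase 0 to 1 for H3K27ac. The cause was not tested.

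Same-numbered replicates were not shown to be paired: the replicate differences of the 2 genotypes correlated across regions between -0.0611 and 0.0733. The promoter analysis with transcription start distances of 1 kb and 2.5 kb was not run. Depth is unknown, so what it limits cannot be given.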

Other observations

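Regions with a peak in all 8 libraries of 1 genotype and none of the other, the 1 Mb windows, the correlations between marks and the test of complete DNA loss were chosen only after results had been seen; the window test with the same number of peaks was set before its value was seen.

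In all, 87 regions had a peak in all 8 libraries of 1 genotype and none of the other, 47 higher and 40 lower in KDM4A-OE, and 41 lay within 1 Mb of another of the same direction. With all peaks, the real count was 4 for H3K4me1 (highest other split 140), 39 for H3K4me2 (44), 31 for H3K4me3 (4), 2 for H3K9ac (7) and 11 for H3K27ac (3). As many were found in 6, 2, 1, 3 and 1 of 100 splits. So large a count was thus uncommon among the splits for each mark but H3K4me1, where each mark is read alone without adjustment over the marks. Chance is not excluded by this. For H3K4me2 and H3K9ac the highest other split exceeded the real count. The other splits were not kept balanced within phase, as the real one is. With the same number of widest peaks the counts were 7 (highest other 5), 47 (4), 7 (1), 2 (1) and 12 (4), each reached by 1 of 100 splits, the real one.

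In 1 Mb windows, H3K4me2 changed most often with genotype: 71 windows were higher and 88 lower in KDM4A-OE of 2456 tested with limma. H3K4me1 had 7 higher and 4 lower, H3K4me3 7 and 3, and H3K27ac 4 and 5. These directions are relative to the covered length of each library: 2 of the 3 lower H3K4me3 windows, at 2000001 to 3000000 on chromosome 1 and 12000001 to 13000000 on chromosome 19, had more covered length in KDM4A-OE before scaling (48.4 against 47.3 kb and 71.5 against 67.1 kb). H3K9ac had 0, with 200 of 1965 tested windows at an unadjusted limma p under 0.05. Windows at 176000001 to 177000000 on chromosome 1 and at 68000001 to 69000000 on chromosome 7 were higher, and the window at 217000001 to 218000000 on chromosome 1 was lower, in H3K4me1, H3K4me2 and H3K27ac alike (hg19). With the same number of widest peaks the H3K4me2 and H3K27ac calls in these windows passed, and the H3K4me1 calls did not (limma adjusted p = 0.0753, 0.0850 and 0.0917), although the H3K4me1 log2 difference went from 0.76 to 0.78, from 0.82 to 0.68 and from -0.69 to -0.80. As many windows were found in 2 of 100 splits for H3K4me1 (11 real, highest other 95), 3 for H3K4me2 (159, 527), 4 for H3K4me3 (10, 218) and 6 for H3K27ac (9, 240). So large a count was thus uncommon among the splits for H3K4me1, H3K4me2 and H3K4me3, where each mark is read alone without adjustment over the marks. Chance is not excluded for any of these marks. For H3K9ac the real count of 0 makes the comparison with other splits void (100 of 100, highest other 227). Splits that call several times the real count point to another structure of the samples, which was not identified.

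These window counts moved with single libraries. For H3K4me3 the count was 0 without any 1 of the 4 Ctrl replicate 1 libraries, the KDM4A-OE G1 libraries or the KDM4A-OE replicate 2 libraries of early S, late S and G2/M, and 171 without Ctrl late S replicate 2. For H3K4me2 it lay between 73 without Ctrl G2/M replicate 1 and 413 without KDM4A-OE early S replicate 1. For H3K4me1 it lay between 5 without Ctrl early S replicate 1 and 30 without KDM4A-OE G2/M replicate 1, and was 1 with the same number of widest peaks. For H3K27ac it lay between 0, without Ctrl G1 replicate 1 among others, and 18 without Ctrl G1 replicate 2.

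By phase, limma called 0 windows in each mark. At an unadjusted limma p under 0.05 were 120 of 2332 tested for H3K4me1, 147 of 2456 for H3K4me2, 66 of 1992 for H3K4me3, 75 of 1965 for H3K9ac and 249 of 2214 for H3K27ac. A count of 0 is reached by each split by definition (100 of 100), so the splits say nothing about chance by phase; their highest others were 72, 219, 238, 47 and 134.

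The window on chromosome 4 from 161000001 to 162000000 (hg19) had 4.18 ± 4.21 kb of H3K4me2 in KDM4A-OE and 65.7 ± 11.9 kb in Ctrl (SD, n = 8 each), a log2 difference of -3.99 (limma adjusted p = 3.49e-05), and H3K4me1 was lower there too, at -2.42. All 5 marks had less covered length there in KDM4A-OE, with 10.7% of the Ctrl length for H3K4me1 (SE 3.63), 6.35% for H3K4me2 (SE 2.27), 13.6% for H3K4me3, 16.4% for H3K9ac and 9.12% for H3K27ac, while the windows on either side held between 97.5% and 170% of it. With the same number of widest peaks the H3K4me2 window still passed (limma adjusted p = 1.19e-05), which argues against the called amount as its cause. Complete loss of the DNA cannot be told apart from a smaller change: the fall of all 5 marks with the sides kept is what a loss would give, but 8 of 8 KDM4A-OE libraries had an H3K4me2 peak there, 6 an H3K4me1, 5 an H3K9ac, 4 an H3K4me3 and 2 an H3K27ac peak, and without reads misplaced peaks cannot be separated from remaining DNA. Loss in part of the cells or of part of the window, a difference between the 2 cell lines that predates KDM4A and an effect of KDM4A stay open and were not tested, as each line is 1 genotype.

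Over the 16 libraries per mark, matched by label, covered length of H3K4me1 and H3K4me2 rose together (Pearson r = 0.901, Spearman rho = 0.859, permutation p = 4.00e-05 for each, adjusted over 10 relations p = 4.00e-04), with r = 0.785 without the 2 farthest samples, 0.559 in Ctrl alone and 0.946 in KDM4A-OE alone. By r, 3 more of the 10 relations passed: H3K4me1 with H3K27ac (r = 0.702, permutation adjusted p = 0.0137), H3K4me2 with H3K27ac (r = 0.595) and H3K4me3 with H3K9ac (r = 0.571, permutation adjusted p = 0.0397 for both). By rho the last 2 did not (permutation adjusted p = 0.0535 and 0.0575), and H3K4me2 with H3K9ac did (permutation adjusted p = 0.0311). For H3K4me3 with H3K9ac, r was 0.502 in replicate 1 but 0.0822 in replicate 2, and 0.667 in Ctrl and 0.529 in KDM4A-OE. For H3K4me2 with H3K27ac, r was 0.388 in Ctrl and 0.924 in KDM4A-OE, and 0.454 without the 2 farthest samples. H3K4me1 and H3K4me3 did not rise together (r = 0.0715, rho = 0.309, permutation p = 0.794 and 0.245), but r was 0.427 without the 2 farthest samples, so the r near 0 rests on those. Peaks of all 80 libraries shared 81 stretches, or 0.0576 Mb of the 426 Mb in a peak of any library, and 0.0440 Mb of these lay on scaffolds outside the chromosomes.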
